A study of Mus musculus with 12 samples.

How the data were processed

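Total RNA from mouse heart cardiomyocytes was sequenced in 12 libraries, and per the labels' protocols the RNA came from cultured cardiomyocytes, was extracted with TRIzol and was made into stranded libraries after ribosomal RNA depletion. Per the labels, all libraries belong to the same batch, but libraries of the 2 deposited tables differed in background reads and spread, as given below. The authors deposited gene counts, as whole numbers per gene symbol and library with no normalization, in 2 tables of 6 libraries each. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic and aligned with HISAT2 to mm10. The counting program, its annotation and its strand setting are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads shared by near-identical genes could be split or dropped. Of the 25239 gene symbols in each table, 25041 (99.2%) matched the RefSeq annotation of GRCm38.p6, the assembly that mm10 is based on, which gave the identifiers, coordinates (counted from 1) and gene types. The tables hold 0 mitochondrially encoded genes.

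Samples were grouped by the genotype names in their titles into Ctrl, Chaf1a cko, Ctrl 3M and Chaf1a cko 3M, with 3 libraries each. The groups, comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Each set of 6 libraries was fitted alone in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and glmQLFit with robust estimation and glmQLFTest compared Chaf1a cko with Ctrl, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 22965 genes in the first set and 13925 in the 3M set. The difference of the effect between the sets was the interaction of set and genotype in a fit of all 12 libraries, from which no effect of set was read. CPM values were scaled by the TMM factors. The exceptions are the shares of counts, the sums of globin copies, and the sums of Y-linked genes and Xist, which are relative to the library total. Total counts per library were 15068468, 19047467 and 20896673 in Ctrl, 16529103, 18789131 and 20879414 in Chaf1a cko, 11262660, 16445963 and 12561947 in Ctrl 3M and 10569325, 15600479 and 15432327 in Chaf1a cko 3M. The standard errors and intervals at this depth hold counting error and the spread between libraries.

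There were 38 gene lists: CAF-1 and histone chaperones, DNA replication and S phase, G2 and mitosis, cytokinesis, p53 targets and DNA damage, replication-dependent histones, replacement histones, cardiac stress and natriuretic genes, fetal sarcomere isoforms, adult cardiomyocyte and sarcomere genes, calcium handling and ion channels, fatty acid oxidation, oxidative phosphorylation and Krebs cycle, glycolysis, integrated stress response and one-carbon, unfolded protein and heat shock, NRF2 and oxidative stress, interferon response, inflammatory cytokines and chemokines, extracellular matrix and fibrosis, YAP targets, skeletal muscle lineage, neuronal lineage, Hox genes, cardiac transcription factors, atrial genes, sex-linked check genes, mitochondrially encoded genes, immediate early and dissociation genes, and markers of fibroblasts, endothelium, mural and smooth muscle, macrophages and myeloid cells, lymphocytes, erythroid and blood cells, Schwann cells and nerve, epicardium and mesothelium, and adipocytes. Of 1010 listed members 989 were in the tables. The mitochondrially encoded list could not be tested, as it had 0 members in the tables. Some genes stand in more than 1 list. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a set. Members past the threshold were counted over all genes and adjusted over the list alone. Shares of counts per list were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

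The genes named were Chaf1a, the 8 that rose and the 8 that fell most among called genes with a mean log2 CPM of at least 1 and no overlap between groups, leaving out predicted and unnamed loci and the sex-linked check genes, and up to 4 members of each list described. List members were those with the smallest p, or the most abundant ones where fewer than 2 were called. The 6 genes with the smallest adjusted p of the difference between the sets completed the rule. From lists without called members, fewer than 4 members were given. Genes named beside a count of a few genes, and Btbd35f1, Gm15093, Plin4, Myom2 and Fos in the 3M set, were chosen after their values were seen.

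Alternatives were DESeq2 size factors, library size alone, the Wald test of DESeq2 1.42.0, no filter beyond a total above 0, a filter of at least 10 CPM in at least 3 libraries, glmTreat against a fold change of 1.5, a replicate block and leaving out each library in turn. Added after the data were seen were a filter on the chemoreceptor background, a fit without Rn45s and Lars2, and the marker shares without each library. Leaving out mitochondrially encoded genes was void. A sex covariate was not run, since each first-set library held reads of Xist and of Y-linked genes and the 3M libraries were of 1 sex pattern. Replicate pairs were compared by a chi-square test per gene, and no pair within a group differed by as little as sampling noise, which does not show whether the libraries came from separate RNA. Each library was entered as 1 replicate. The code was tested on simulated counts with the means, depths and spread of each set and 200 changed genes. In the first set, 14 of 100 genes changed 1.5-fold and 60 of 100 changed 3-fold were recovered, with 7 of 81 calls on unchanged genes among 22965 genes.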

Results

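RNA was sequenced from mouse heart cardiomyocytes in 12 libraries that form 4 groups of 3. The study compared mice in which Myh6-Cre, a Cre recombinase driven by a cardiomyocyte promoter, acts on floxed Chaf1a alleles with mice that carry the floxed alleles and no Cre, so the presence of Cre and the genotype go together. The deposited counts name the control libraries WT, without naming the floxed alleles. Chaf1a encodes the large subunit of chromatin assembly factor 1 (CAF-1), the histone chaperone that places new histones on replicated DNA. The title names perinatal loss of Chaf1a and polyploid cardiomyocytes as the subject. One table held the groups Ctrl and Chaf1a cko, called the first set here, and a separate table held Ctrl 3M and Chaf1a cko 3M, called the 3M set. The labels do not spell out 3M and give no age for the first set, and levels were not compared between the tables. Library totals ran from 15068468 to 20896673 counts in the first set and from 10569325 to 16445963 counts in the 3M set. The names of the 3M libraries each hold a different number, but the labels do not say what it numbers. Nothing in the labels says that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

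The spread between libraries of a group differed between the tables. Among genes with a mean above 10000 counts the median coefficient of variation was 2.21% in Ctrl and 2.83% in Chaf1a cko of the first set, and 20.8% in Ctrl 3M and 12.4% in Chaf1a cko 3M. The first table also held reads in nearly all genes. Of 1470 chemoreceptor genes, taken here as mostly silent in heart cells, 94.9% to 97.8% had counts in each library of the first set and 1.09% to 1.63% in each library of the 3M set. Their median level in the first set was 1.66 CPM (counts scaled to library size) and their 95th percentile was 5.31 CPM, which serves here as the background level of that table. Summed counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in the first set were 60.6, 52.8 and 50.7 CPM in Ctrl replicates 1 to 3 and 135, 122 and 111 CPM in Chaf1a cko replicates 1 to 3. Background was not subtracted from these sums, and in Ctrl Kdm5d and Uty were near it, at 5.77 and 7.77 CPM. Xist, the noncoding RNA of the inactive X chromosome, was present in each of these libraries at 262 CPM or more. Reads of Xist and of Y-linked genes thus occurred in every library, and the level of Y-linked reads differed between the groups. Differences between the first-set groups below therefore cannot be told apart from a difference in sex mixture.

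**Figure D1:**
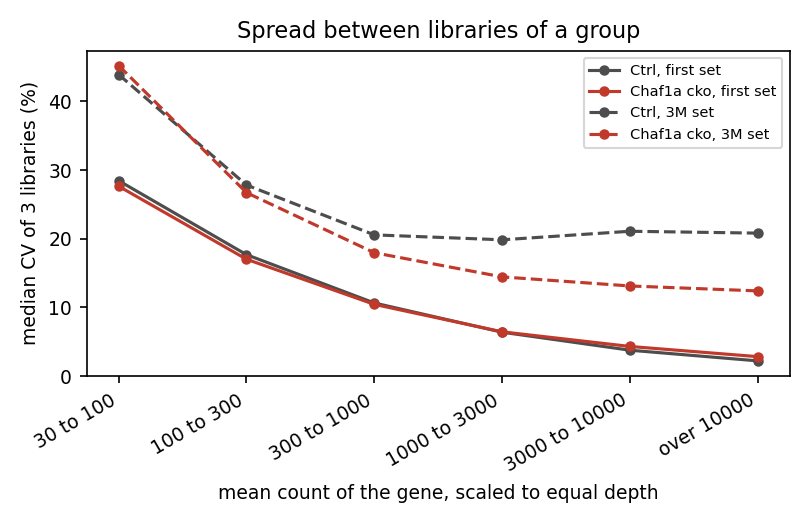
Median coefficient of variation in percent (vertical axis) over the 3 libraries of a group, for genes grouped by mean count scaled to equal depth (horizontal axis), with solid lines for the first set and dashed lines for the 3M set. Above 10000 counts the medians were 2.21% and 2.83% in the first set against 20.8% and 12.4% in the 3M set.

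Chaf1a, the targeted gene, was not lower in the libraries labelled Chaf1a cko. Chaf1a (Entrez gene 27221, protein coding) lies on chromosome 17 from 56040416 to 56068026 in mm10. In the first set it was at 22.7, 32.3 and 18.8 CPM in Ctrl replicates 1 to 3 and at 29.0, 24.5 and 22.0 CPM in Chaf1a cko replicates 1 to 3. The means were 24.6 ± 6.93 CPM in Ctrl and 25.1 ± 3.56 CPM in Chaf1a cko (SD, n = 3 each). The log2 fold change was 0.03 with a standard error (SE) of 0.18 and a 95% interval from -0.36 to 0.42, with an adjusted p of 0.981 in edgeR's quasi-likelihood test. In the 3M set Chaf1a was at 1.88, 4.74 and 9.75 CPM in Ctrl 3M and at 8.34, 5.58 and 5.54 CPM in Chaf1a cko 3M, with means of 5.45 ± 3.99 and 6.49 ± 1.61 CPM (SD, n = 3 each). The log2 fold change there was 0.25 (SE 0.61, 95% interval -1.13 to 1.63, adjusted p 0.952 in edgeR). The tables count reads per gene, so reads from exons outside the floxed part and from cells without Cre enter these values, and the floxed exons are not given in the sources used here. Every direction below is therefore that of the libraries labelled Chaf1a cko against those labelled Ctrl. The sign of the first-set value turned when Ctrl replicate 1 (-0.02), Ctrl replicate 3 (-0.13) or Chaf1a cko replicate 1 (-0.09) was left out, and that of the 3M value when Ctrl 3M replicate 1 (-0.16) was left out.

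**Figure D2:**
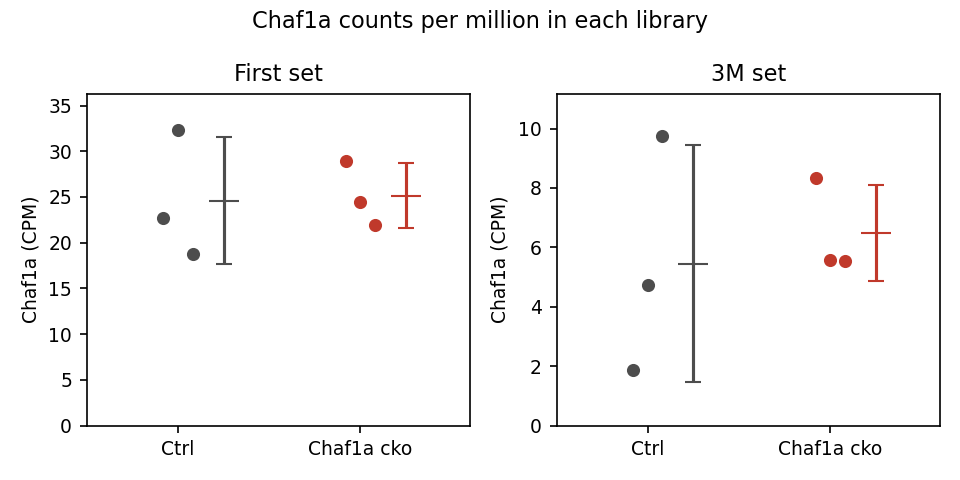
Chaf1a in CPM (vertical axis) in each library (points) of the first set and the 3M set, with the mean and SD of the 3 libraries of each group beside them. The means were 24.6 in Ctrl and 25.1 in Chaf1a cko of the first set, and 5.45 and 6.49 in the 3M set.

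In the first set, genes for histones, mitosis and glycolysis rose in the libraries labelled Chaf1a cko, while atrial and immediate early genes fell. Tal1, a transcription factor of blood and endothelial development, rose from 9.37 ± 1.29 to 26.5 ± 1.47 CPM (2.83-fold, SE of the log2 fold change 0.17, adjusted p 7.7e-05). Casq1, the calsequestrin of fast skeletal muscle, rose from 27.3 ± 3.55 to 57.6 ± 1.40 CPM (log2 fold change 1.08, SE 0.12, adjusted p 4.3e-05). Sln, which encodes sarcolipin, an inhibitor of the calcium pump in atrial and skeletal muscle, fell from 11.5 ± 1.53 to 3.23 ± 0.413 CPM (-1.83, SE 0.25, adjusted p 0.000531). Values are means ± SD of 3 libraries, log2 fold changes are those of Chaf1a cko over Ctrl, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 22965 tested genes. The test called 270 genes, 170 higher and 100 lower, and 2326 genes had an unadjusted p under 0.05. The changes were small: the median fold of the called genes was 1.35, and 26 of them changed by more than 2-fold. The CPM ranges of the groups did not overlap in 3716 genes, 16.2% of those tested, where chance gives 10%. The count of called genes was 132 without Ctrl replicate 2, 163 without Ctrl replicate 3, 80 higher and 57 lower without Chaf1a cko replicate 1, 128 without Chaf1a cko replicate 2 and 132 without Chaf1a cko replicate 3. The balance of directions shifted too, with 148 higher and 53 lower without Ctrl replicate 1, and 191 higher and 175 lower with a filter of 10 CPM. Lower calls numbered 58 without Ctrl replicate 2, 61 without Ctrl replicate 3, 49 without Chaf1a cko replicate 2 and 53 without Chaf1a cko replicate 3. DESeq2's Wald test called 490 genes, 320 higher and 170 lower, and a test against a fold change of 1.5 (glmTreat) called 3.

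Among the genes with the largest rises, 4 were histone genes. H3f4 (Entrez gene 382523, chromosome 11, 58961711 to 58962273) rose from 2.09 ± 1.22 to 7.38 ± 1.05 CPM (log2 fold change 1.81, adjusted p 0.0230 in edgeR). H4c12 (chromosome 13, 21750145 to 21750553) rose from 6.64 ± 2.57 to 16.4 ± 0.291 CPM (1.30). H3c1 (chromosome 13, 23761885 to 23762386) rose from 5.94 ± 0.674 to 13.4 ± 1.75 CPM (1.17), and H1f5 (chromosome 13, 21779832 to 21780625), a linker histone, from 22.9 ± 4.01 to 47.0 ± 4.78 CPM (1.03). Core histone genes are near-identical copies, so their single values are uncertain where reads could be shared. Tceal7, on the X chromosome, rose by 1.69 and Bdh1, a mitochondrial enzyme of ketone body use, rose by 1.40 on the log2 scale. Tal1 lies on chromosome 4 from 115056426 to 115071755, Casq1 on chromosome 1 from 172209894 to 172219895 and Sln on chromosome 9 from 53850251 to 53853849. Among the genes with the largest falls, Clec4d fell by 2.03, Cacna2d2, an auxiliary subunit of voltage-gated calcium channels, fell by 1.29, Actg2, the smooth muscle gamma actin, fell by 1.25, Fgf12 fell by 1.09 and P2ry4, a nucleotide receptor, fell by 0.99 on the log2 scale. Hoxaas2, a noncoding gene antisense to Hox genes, fell by 2.22, and the strand setting of the counting is not given in the sources used here, so its reads cannot be told from those of its partners. Btbd35f2, a member of a multigene family on the X chromosome, fell by 1.46 and is uncertain for the same reason as the histones. H3f4, Hoxaas2 and Clec4d had mean levels over the 6 libraries below the background of 5.31 CPM, which held for 9 of the 270 called genes.

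Histone and cell division genes rose as groups. Of 46 replication-dependent histone genes, which are made in S phase, 16 rose, 0 fell and 30 did not pass, and 32 rose when adjusted over the list alone. The list's median log2 fold change was 0.51, and its camera test gave an adjusted p of 3.2e-40 with a preset correlation and an adjusted p of 0.00300 with an estimated correlation. H2ac18 rose from 163 ± 6.51 to 223 ± 15.8 CPM (0.45, SE 0.06) and H1f3 from 43.3 ± 2.35 to 65.3 ± 2.22 CPM (0.59, SE 0.10), while H2bc15 rose by 0.75. Of 60 genes of G2 and mitosis, 10 rose, 0 fell and 50 did not pass, with 31 higher when adjusted over the list alone (median 0.33; camera adjusted p 2.3e-26, and 0.00300 with an estimated correlation). Mki67, the proliferation marker, rose from 609 ± 2.06 to 784 ± 8.91 CPM (0.36, SE 0.04, adjusted p 1.4e-05 in edgeR) and Top2a, the mitotic topoisomerase, from 149 ± 4.71 to 200 ± 9.46 CPM (0.42, SE 0.06). Hmmr and Nuf2, a spindle and a kinetochore gene, rose by 0.55 and 0.75. Of 26 cytokinesis genes 2 rose and 0 fell (10 higher when adjusted over the list alone), namely Anln (0.52) and Septin7 (0.26), with a camera adjusted p of 3.6e-09 and an adjusted p of 0.0415 with an estimated correlation. Of 52 genes of DNA replication and S phase 1 rose and 0 fell (6 higher when adjusted over the list alone), with a camera adjusted p of 2.6e-07 and an adjusted p of 0.0215 with an estimated correlation. The gene that rose was Dnmt1, the maintenance DNA methyltransferase, at 79.8 ± 4.50 against 105 ± 8.33 CPM (0.39). The next most abundant members did not pass, with log2 fold changes of 0.20 for Rrm1, 0.40 for Pcna (adjusted p 0.0952) and -0.01 for Rfc1. Of 21 CAF-1 and histone chaperone genes 2 rose and 0 fell, the same number as adjusted over the list alone. These were Nap1l1, from 59.4 to 102 CPM (0.78, SE 0.13), and Dnajc9, from 12.8 ± 0.513 to 21.9 ± 1.42 CPM (0.77), both histone chaperone genes. That list passed with a preset correlation (camera adjusted p 0.000294) and with fry (adjusted p 0.00358). It did not pass with an estimated correlation (camera adjusted p 0.0521). Of 11 replacement histone genes 0 passed, also adjusted over the list alone (camera adjusted p 0.00226; adjusted p = 0.161 with an estimated correlation). The Y-linked genes rose in the same libraries, as given below.

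Cardiac genes moved in both directions. Of 16 atrial genes, 1 rose, 9 fell and 6 did not pass, and 1 rose and 12 fell when adjusted over the list alone. The median was -0.67, with a camera adjusted p of 9.6e-26 and an adjusted p of 0.00400 with an estimated correlation. Nr2f2, a transcription factor that sets atrial identity, fell from 82.0 ± 5.22 to 41.4 ± 2.58 CPM (-0.98, SE 0.10, adjusted p 1.1e-05 in edgeR). Myl4, an atrial myosin light chain, fell from 336 ± 6.25 to 223 ± 9.86 CPM (-0.59, SE 0.05) and Pam, an enzyme that amidates peptides, from 1265 ± 8.67 to 990.3 ± 8.77 CPM (-0.35, SE 0.03). The member that rose was Nppa, which encodes atrial natriuretic peptide, from 779 ± 23.8 to 1174 ± 39.0 CPM (0.59, SE 0.04, adjusted p 1.1e-07). Of 30 cardiac stress and natriuretic genes 3 rose and 4 fell (5 and 4 when adjusted over the list alone; camera adjusted p 0.130). With Nppa rising, Xirp1, an intercalated disc protein gene, fell from 527 ± 18.7 to 325 ± 18.7 CPM (-0.70, SE 0.05), Flnc, which encodes filamin C, from 881 ± 22.3 to 643 ± 11.4 CPM (-0.46, SE 0.04) and Atf3, a stress transcription factor, fell by 0.57. Of 20 fetal sarcomere isoforms 5 rose and 3 fell (6 and 3 when adjusted over the list alone; camera adjusted p 0.0679), among them Acta2, the smooth muscle alpha actin, from 584 ± 21.8 to 854 ± 10.7 CPM (0.55, SE 0.04). Of 29 adult cardiomyocyte and sarcomere genes 3 rose and 6 fell (9 and 7 when adjusted over the list alone; camera adjusted p 0.846), with a median of 0.02 and a mean of -0.04. The share of all counts in this list was 11.5% ± 0.0939 in Ctrl and 10.7% ± 0.252 in Chaf1a cko (SD, n = 3 each, exact two-sided permutation p = 0.1). Myh6, the main adult myosin heavy chain and the source of the Cre promoter, fell from 40460 ± 232 to 37062 ± 211 CPM (-0.13, SE 0.01, adjusted p 1.1e-06). Ttn, which encodes titin, fell by 0.12, Atp2a2, the calcium pump of the sarcoplasmic reticulum, by 0.28 and Ryr2, the calcium release channel, by 0.24. Of 37 calcium handling and ion channel genes 0 rose and 3 fell (3 and 5 when adjusted over the list alone; camera adjusted p 0.0562): Atp2a2, Ryr2 and Kcnj3, an atrial potassium channel, which fell by 0.74. Of 28 cardiac transcription factors 1 rose, Hey2 (0.48), the same number as adjusted over the list alone (camera adjusted p 0.587).

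Genes of energy metabolism shifted by small amounts. Of 27 glycolysis genes 6 rose and 0 fell, with 12 higher when adjusted over the list alone (camera adjusted p 3.0e-09; adjusted p = 0.0215 with an estimated correlation). Eno1 rose from 193 ± 8.30 to 280 ± 9.11 CPM (0.53, SE 0.05, adjusted p 2.2e-05 in edgeR), Ldha, which makes lactate, from 318 ± 11.2 to 441 ± 9.30 CPM (0.47, SE 0.05), Pgk1 from 234 ± 6.79 to 315 ± 13.8 CPM (0.43) and Gpi1 by 0.32. Of 64 genes of oxidative phosphorylation and the Krebs cycle 3 rose and 0 fell, namely Sdhb (0.27), Cs (0.20) and Mdh2 (0.17), with 16 higher when adjusted over the list alone (camera adjusted p 3.3e-05; adjusted p = 0.202 with an estimated correlation). Of 37 fatty acid oxidation genes 0 rose and 4 fell, with 7 lower when adjusted over the list alone (camera adjusted p 0.00122; adjusted p = 0.161 with an estimated correlation). The 4 were Pdk4, which restrains glucose oxidation (-0.45), Acot2 (-0.46), Acaa2 (-0.31) and the fatty acid carrier Cd36 (-0.21).

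Among matrix, fibroblast and immediate early genes more members fell than rose, and of these lists only the immediate early list passed with an estimated correlation. Of 20 fibroblast markers 1 rose and 6 fell, and 2 rose and 8 fell when adjusted over the list alone (median -0.29; camera adjusted p 4.1e-06; adjusted p = 0.0723 with an estimated correlation). Dcn, which encodes decorin, fell from 94.3 ± 2.09 to 60.2 ± 2.31 CPM (-0.65, SE 0.08, adjusted p 0.000148 in edgeR) and Col1a1, a chain of collagen I, from 1106 ± 19.3 to 846 ± 26.5 CPM (-0.39, SE 0.03). The share of all counts in the fibroblast markers was 0.410% ± 0.00205 in Ctrl and 0.345% ± 0.00546 in Chaf1a cko (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Of 39 genes of extracellular matrix and fibrosis, a list that also holds the collagens and Dcn, 4 rose and 9 fell, and 7 rose and 13 fell when adjusted over the list alone (camera adjusted p 0.000573; adjusted p = 0.214 with an estimated correlation). Col1a2 and Col3a1 fell by 0.36 and 0.23, and Eln, which encodes elastin, by 0.32. Of 19 YAP targets 0 rose and 3 fell, namely Ccn1, from 322 ± 6.21 to 222 ± 12.6 CPM (-0.54, SE 0.05), Amotl2 (-0.31) and Ccn2 (-0.26), with 1 higher and 7 lower when adjusted over the list alone (camera adjusted p 0.000573; adjusted p = 0.119 with an estimated correlation). Of 26 immediate early and dissociation genes 0 rose and 7 fell, with 13 lower when adjusted over the list alone (camera adjusted p 3.1e-12; adjusted p = 0.0242 with an estimated correlation). Egr1 fell from 469 ± 10.7 to 328 ± 11.6 CPM (-0.51, SE 0.05), Fos from 566 ± 15.5 to 425 ± 17.5 CPM (-0.41, SE 0.04) and Jun by 0.33. Markers of other cell types, whose cells could also be in these preparations, did not pass the camera test as lists. The share of counts in mural markers rose from 0.247% ± 0.00447 to 0.283% ± 0.00712 (exact p = 0.1), that in macrophage markers fell from 0.0219% to 0.0204% (exact p = 0.1) and that in endothelial markers was 0.477% and 0.468% (exact p = 0.6). Of 22 endothelial markers 0 rose and 1 fell, Aqp1 (-0.36), with 3 lower when adjusted over the list alone (camera adjusted p 0.486). Of 14 mural and smooth muscle markers 2 rose, Acta2 and Cnn1 (0.75), and 1 fell, Myh11, the smooth muscle myosin (-0.41), with 4 and 1 when adjusted over the list alone (camera adjusted p 0.0899). Of 24 macrophage and myeloid markers 0 passed, also adjusted over the list alone (camera adjusted p 0.389), and 13 had a mean above the background.

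Among the sex-linked check genes of the first set, 4 of 6 rose and 0 fell, the same number as adjusted over the list alone (camera adjusted p 8.7e-11; adjusted p = 0.0415 with an estimated correlation). Ddx3y rose from 30.2 ± 6.12 to 65.2 ± 8.82 CPM (1.12, adjusted p 0.000200 in edgeR), Eif2s3y by 1.25, Uty by 1.26 and Kdm5d by 1.30. Of 35 interferon response genes 0 passed, also adjusted over the list alone, yet the list passed the camera test (adjusted p 0.00146) and not with an estimated correlation (adjusted p = 0.0609 with an estimated correlation). Its member Gbp3 had a log2 fold change of 0.35, with an adjusted p of 0.206. In 4 further lists 1 member rose and 0 fell. These were Shmt2 (0.49) among 30 genes of the integrated stress response and one-carbon metabolism (camera adjusted p 0.855), Hsp90b1 (0.23) among 19 of the unfolded protein and heat shock response (0.894), Mt1 (0.58) among 20 of NRF2 and oxidative stress (0.765), and Krt18 (0.94) among 11 epicardial and mesothelial markers (0.434). Adjusted over the list alone, these lists had 1, 4, 2 and 1 members higher, and the unfolded protein list had 2 lower. Casq1 was the 1 member that rose among 29 skeletal muscle lineage genes, with 1 higher and 2 lower when adjusted over the list alone (camera adjusted p 0.472). No member was called in the remaining lists. Their camera adjusted p-values were 0.238 for p53 targets and DNA damage (40 genes, Plk2 at -0.06), 0.667 for inflammatory cytokines and chemokines (26), 0.238 for neuronal lineage genes (30), 0.895 for Hox genes (29), 0.765 for lymphocyte markers (12), 0.228 for erythroid and blood genes (10), 0.903 for Schwann and nerve markers (10) and 0.163 for adipocyte markers (12). Members with a mean above the background of 5.31 CPM numbered 35, 17, 20, 2, 2, 7, 4 and 4 in the same order. Lists mostly below the background, such as Hox genes, were therefore hardly tested. Adjusted over the list alone, 1 cytokine gene was lower, 1 erythroid gene was higher and 0 others passed. Globin was also summed over near-identical copies after the results were seen, since counts moved between them within groups. Hba-a1 plus Hba-a2 was at 1579.8, 1525 and 1523 CPM in Ctrl and 2155, 2141 and 2090 CPM in Chaf1a cko. Hbb-b1, which is not in the list, plus Hbb-bs was at 638, 600 and 618 against 860, 904 and 800 CPM. These sums were not tested. The median, the mean and the direction of the test did not share a sign for adult cardiomyocyte genes, integrated stress response, unfolded protein, lymphocyte, erythroid, Schwann and epicardial lists. None of these lists passed the camera test. Of 37 lists with tested members, 16 passed with the preset correlation, 10 of them higher and 6 lower, and 8 passed with an estimated correlation. With fry 21 passed, 12 higher and 9 lower.

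**Figure D3:**
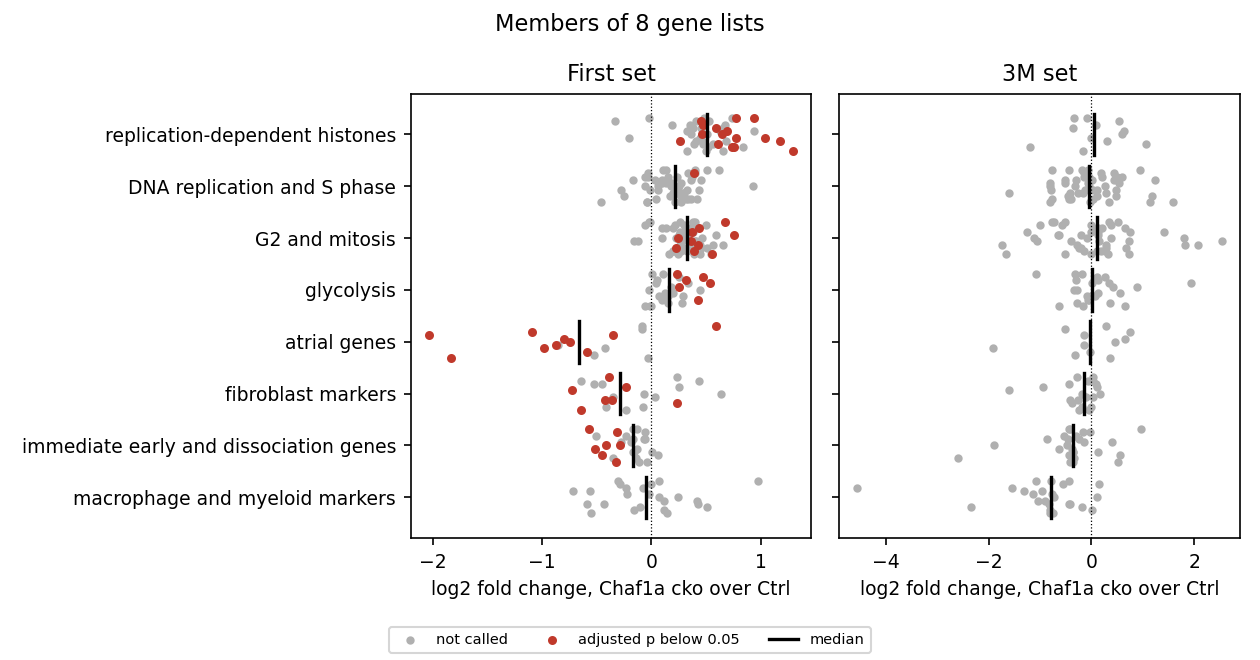
Log2 fold change of Chaf1a cko over Ctrl (horizontal axis) for each tested member of 8 gene lists in the first set and the 3M set, with members past the adjusted p threshold of 0.05 in red, the others in grey and the list median as a black line. In the first set the medians were 0.51 for replication-dependent histones, 0.33 for G2 and mitosis and -0.67 for atrial genes, and in the 3M set the median of macrophage and myeloid markers was -0.79 with 0 members called.

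In the 3M set 2 genes were called between the libraries labelled Chaf1a cko 3M and Ctrl 3M. Apbb2, an adaptor protein gene that binds the amyloid precursor protein (Entrez gene 11787, chromosome 5, 66298725 to 66619064), rose from 11.3, 9.36 and 4.64 CPM to 143, 124 and 146 CPM (log2 fold change 4.03, SE 0.34, adjusted p 0.0140 in edgeR's quasi-likelihood test). Slc38a10, an amino acid transporter gene (Entrez gene 72055, chromosome 11, 120103951 to 120151351), fell from 112 ± 17.5 to 24.8 ± 3.56 CPM (SD, n = 3 each; -2.17, SE 0.22, adjusted p 0.0300). The 3 libraries of each group did not overlap for either gene. Of 13925 tested genes, 965 had an unadjusted p under 0.05, and the CPM ranges did not overlap in 1964 genes (14.1%, where chance gives 10%). DESeq2's Wald test called 78 genes, 32 higher and 46 lower. In simulated counts with the spread of this set, 12 of 100 genes changed 3-fold and 0 of 100 changed 1.5-fold were recovered, and 4 of 16 calls were unchanged genes. Leaving out 1 library ended calls while the log2 fold changes stayed between 3.74 and 4.29 for Apbb2 and between -2.29 and -2.04 for Slc38a10. Without Chaf1a cko 3M replicates 1, 2 or 3 the adjusted p of Apbb2 was 0.0996, 0.0550 and 0.0568, and that of Slc38a10 was 0.214, 0.136 and 0.288. For Slc38a10 it was 0.0557 without Ctrl 3M replicate 2 and 0.0676 without Ctrl 3M replicate 3. The number of called genes was 5 without Ctrl 3M replicate 1, 4 without Ctrl 3M replicate 2 and 4 without Ctrl 3M replicate 3. It was 0 without Chaf1a cko 3M replicate 1, 0 without Chaf1a cko 3M replicate 2 and 1 without Chaf1a cko 3M replicate 3.

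As groups, Hox genes, macrophage markers and matrix genes were lower in the libraries labelled Chaf1a cko 3M, with 0 members called by edgeR in any list and 0 lists passing with an estimated correlation. Of 10 tested Hox genes all 10 had a negative log2 fold change, 0 were called and 4 were lower when adjusted over the list alone (median -2.36; camera adjusted p 6.3e-12; adjusted p = 0.604 with an estimated correlation). Hoxb3 was at 11.4 ± 2.90 against 3.69 ± 1.22 CPM (-1.62, adjusted p 0.569) and Hoxb4 at 11.6 ± 6.58 against 1.40 ± 0.833 CPM (-3.07, adjusted p 0.522). Of 24 macrophage and myeloid markers 21 were negative, 0 were called and 1 was lower when adjusted over the list alone (median -0.79; camera adjusted p 1.0e-07; adjusted p = 0.604 with an estimated correlation). C1qa, a complement gene of tissue macrophages, was at 95.3 ± 5.62 against 48.8 ± 6.88 CPM (-0.97, SE 0.19, adjusted p 0.458), Lyz2 at 149, 140 and 111 against 92.0, 85.0 and 51.7 CPM (-0.81), C1qb at 64.2 ± 11.4 against 38.2 ± 3.47 CPM (-0.75) and Mrc1 at 62.2 ± 13.3 against 37.6 ± 7.43 CPM (-0.73). The share of all counts in these markers was 0.0796% ± 0.0133 in Ctrl 3M and 0.0461% ± 0.00375 in Chaf1a cko 3M (exact two-sided permutation p = 0.1). In the same libraries the share in adult cardiomyocyte and sarcomere genes was 5.35% ± 0.845 in Ctrl 3M and 6.83% ± 0.336 in Chaf1a cko 3M, and that in epicardial markers 0.0134% and 0.00792% (exact p = 0.1 for each). Of 37 genes of extracellular matrix and fibrosis 32 were negative, 0 were called, also adjusted over the list alone (camera adjusted p 1.2e-05; adjusted p = 0.704 with an estimated correlation). Col4a1, a basement membrane collagen, was at 1242 ± 190 against 668 ± 220.1 CPM (-0.90), and the log2 fold changes of Col4a2, Sparc and Timp3 were -0.28, -0.06 and 0.55. Of 19 inflammatory cytokine and chemokine genes 18 were negative and 1 was lower when adjusted over the list alone (camera adjusted p 0.000936; adjusted p = 0.604 with an estimated correlation). Of 19 genes of the unfolded protein and heat shock response 16 were negative and 0 passed when adjusted over the list alone (camera adjusted p 0.0178; adjusted p = 0.921 with an estimated correlation). Of 26 immediate early and dissociation genes 21 were negative and 2 were lower when adjusted over the list alone (camera adjusted p 0.0178; adjusted p = 0.625 with an estimated correlation). The cytokine list did not pass without Ctrl 3M replicate 1 (adjusted p 0.0605). The unfolded protein list did not pass without Ctrl 3M replicate 1 (0.684) or Chaf1a cko 3M replicate 1 (0.444), nor did the immediate early list (0.299 and 0.398).

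The matrix and immediate early lists passed the camera test with lower values in both sets only at the preset correlation: with an estimated correlation the adjusted p was 0.214 and 0.704 for matrix and 0.0242 and 0.625 for immediate early genes in the first and the 3M set. The other lists that had moved in the first set did not pass it in the 3M set, with adjusted p-values of 0.777 for 12 replication-dependent histones, 0.619 for 49 genes of G2 and mitosis, 0.497 for 23 cytokinesis genes, 0.971 for 50 genes of DNA replication and S phase, 0.546 for 21 CAF-1 and histone chaperone genes and 0.660 for 11 replacement histones. They were 0.548 for 11 atrial genes, 0.456 for 26 glycolysis genes, 0.163 for 64 genes of oxidative phosphorylation and the Krebs cycle, 0.0778 for 37 fatty acid oxidation genes, 0.830 for 17 YAP targets, 0.993 for 35 interferon response genes, 0.208 for 20 fibroblast markers and 0.163 for 4 sex-linked genes. For cardiac lists they were 0.546 for 28 stress and natriuretic genes, 0.204 for 16 fetal sarcomere isoforms, 0.236 for 29 adult cardiomyocyte genes, 0.0927 for 36 calcium handling and ion channel genes and 0.104 for 26 cardiac transcription factors. Myh6 was at 16212 ± 2595 against 26461 ± 2946 CPM (0.71, SE 0.19, adjusted p 0.587 in edgeR) and Ttn at 3138 ± 1705 against 6389 ± 509.8 CPM (1.03, adjusted p 0.712). The remaining values were 0.546 for 37 p53 targets, 0.811 for 28 genes of the integrated stress response, 0.921 for 20 of NRF2 and oxidative stress, 0.0505 for 11 skeletal muscle lineage genes and 0.675 for 9 neuronal lineage genes. For markers of other cells they were 0.546 for 22 endothelial, 0.124 for 14 mural and smooth muscle, 0.784 for 5 lymphocyte, 0.971 for 8 erythroid, 0.971 for 7 Schwann, 0.0778 for 5 epicardial and 0.971 for 5 adipocyte markers. None of these lists had a called member. Adjusted over the list alone, 1 member was lower in each of the stress, epicardial and sex-linked lists, 1 was higher in each of the fetal sarcomere, adult cardiomyocyte and calcium handling lists, and 0 passed in the others. Signs differed between the median, the mean and the test for DNA replication, adult cardiomyocyte, integrated stress response, interferon, YAP target, atrial, endothelial, Schwann and adipocyte lists.

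The effects in the sets were also compared with each other. No gene was called in both sets in the same direction by edgeR. Of 13856 genes tested in both, 147 were called higher and 84 lower in the first set and 1 in each direction in the 3M set, so 0.0106 and 0.00606 shared calls were expected (one-sided Fisher's exact p of 1 in each direction). DESeq2 gave 2 shared calls: Myom2, an M-band gene of the sarcomere, was higher (0.37 and 1.49) and Fos was lower (-0.41 and -1.91) in both sets, and these genes were looked at after their values were seen. Across genes, which are not independent replicates, the log2 fold changes of the sets had a Pearson r of 0.00768 and a Spearman rho of -0.00265. Among the first-set calls, 66 of 147 higher genes (44.9%) and 45 of 84 lower genes (53.6%) had the same sign in the 3M set.

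The difference of the effect between the sets passed in 15 of 22803 genes, 13 with a larger and 2 with a smaller value in the 3M set, and 2160 genes had an unadjusted p under 0.05. Only 13856 genes passed the filter in each set alone, so many genes of this fit had few counts in 1 set. Apbb2 differed by 4.13 (SE 0.35, adjusted p 0.00259 in edgeR's quasi-likelihood test of the interaction), with log2 fold changes of -0.06 in the first set and 4.03 in the 3M set. Map2k4, a kinase gene upstream of JNK (chromosome 11, 65688244 to 65788359), differed by 2.25 (SE 0.24, adjusted p 0.0120), with 2.12 in the 3M set. Suco (chromosome 1, 161816112 to 161876837) differed by 2.93 (SE 0.41) and Psme4, a proteasome activator gene (chromosome 11, 30771775 to 30881150), by 1.11 (SE 0.16), each with an adjusted p of 0.0487. Atp6ap1l (chromosome 13, 90883439 to 90905355) and Dusp4 (chromosome 8, 34807610 to 34819894) also had an adjusted p of 0.0487, but their 3 Ctrl 3M libraries held 0 counts, so no fold is given. Dusp4 did not pass the filter in the 3M set alone. This fit gave each gene 1 spread for all 12 libraries, although libraries differed more in the 3M set. The SE of the difference was below that of the 3M effect alone for Map2k4 (0.243 against 0.255) and Psme4 (0.158 against 0.176). It was above it for Apbb2 and Suco. The adjusted p-values of the difference may therefore be too small. The count of 15 was 1 without any of Ctrl replicate 1, Ctrl replicate 3 and Chaf1a cko replicates 1, 2 and 3 and was 2 without Ctrl replicate 2. It was 110 without Ctrl 3M replicate 2 (56 larger and 54 smaller), 85 without Ctrl 3M replicate 3 (51 and 34), 51 without Chaf1a cko 3M replicate 1 (27 and 24) and 5 without Chaf1a cko 3M replicate 3 (4 and 1). DESeq2 called 451, 255 larger and 196 smaller, so the balance of 13 to 2 did not hold there. Of 37 lists, 11 differed between the sets in the camera test with the preset correlation, among them Hox genes (adjusted p 3.6e-06). With an estimated correlation 0 differed, and the smallest adjusted p was 0.190. Only 2 of 29 Hox genes had a first-set mean above the background, so their first-set effect was hardly measured.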

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

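The tests of explanations for Chaf1a, for the atrial genes and for the small spread were chosen, and their limits set, after the results were seen.

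Chaf1a was as high in the libraries labelled Chaf1a cko as in Ctrl of the first set, at 25.1 against 24.6 CPM. Background reads stay open as a source. The mean of Chaf1a was 4.69 times the 95th percentile of the chemoreceptor genes, but counts were not scaled to gene length, on which background can depend. Reads from cells without Cre, or from exons that Cre leaves in place, stay open: the lower 95% limit of the log2 fold change was -0.36, and counts per gene show neither cells nor exons. These sources cannot be told apart from a gene that was not deleted. Wrong labels and a true lack of change in the knockout were not tested.

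Atrial genes fell in the first set while Nppa, a member of the same list, rose by a log2 fold change of 0.59. Less atrial tissue raises no transcript of the atria, so it is argued against for Nppa alone, which cells outside the atria can also express. Fewer cells of all other types alike are argued against, since the share of counts in endothelial markers was 0.980 of that in Ctrl and the share in fibroblast markers 0.842, and the lowest endothelial ratio over pairs of libraries (0.931) was above the highest fibroblast ratio (0.860). Less atrial tissue stays open for the other members, of which 15 of 15 had a lower mean, as a lower atrial expression in the same cells would also give. Fewer fibroblasts stay open for part of the genes, since the median fold was 0.819 for fibroblast markers and 0.631 for atrial genes. By share of counts the order was the reverse, with ratios of 0.842 for fibroblast markers and 0.926 for the atrial list, which holds Nppa. An effect of the genotype or of Cre is untested.

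While libraries of a first-set group differed little from each other, single animals of both sexes within a group are argued against. The lowest count of Xist or of the summed Y-linked genes in any library was 913, so each library held reads of both. Background was not subtracted: in Ctrl, Kdm5d and Uty were at 5.77 and 7.77 CPM, near the background of 5.31 CPM, and Ddx3y at 30.2 CPM. Part of the Y-linked reads in Ctrl could thus be background. The Y-linked sums were 50.7 to 60.6 CPM in Ctrl and 111 to 135 CPM in Chaf1a cko, so libraries did not separate into high and low within either group. Repeat libraries of 1 RNA pool per group stay open: the Y-linked genes varied within a group by at most 2.14 times the variance-to-mean ratio of other genes of that abundance (0.966 in Ctrl). The median variance-to-mean ratio rose from 6.62 at 30 to 100 counts to 13.4 above 10000 counts in Ctrl. It rose from 6.21 to 20.7 in Chaf1a cko, from 16.2 to 1181 in Ctrl 3M and from 16.4 to 383 in Chaf1a cko 3M. Counting noise alone would keep this ratio flat and near 1, and every value here was above that, so none of the groups showed counting noise alone. The smaller rise in the first set goes with repeat libraries without deciding. Against such a pool, Xist varied by 122 times that of other genes of its abundance in Ctrl, at 585, 630 and 294 CPM in replicates 1 to 3, and by 5.38 times in Chaf1a cko. Single genes do not decide, since 10 of 3385 genes above 1000 counts varied more than Xist in Ctrl, among them Hba-a1 and Hba-a2. The sum of these copies was 1579.8, 1525 and 1523 CPM in Ctrl while counts moved between them, and 2155, 2141 and 2090 CPM in Chaf1a cko. Pools of several animals per library and biological explanations were not tested.

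The effect of the label differed between the sets in 15 genes by the interaction test, which gave each gene 1 spread for both sets. The difference, 3M minus first set, was 4.13 for Apbb2, 2.25 for Map2k4, 2.93 for Suco and 1.11 for Psme4, and the adjusted p was 0.0487 for Atp6ap1l and 0.0487 for Dusp4, both at 0 counts in Ctrl 3M. Of 100 relabelings of the libraries within the sets, drawn from 200 possible, 3 gave at least 15 genes, the real one included. This share is small, but the rest of the 200 were not run, so it does not exclude chance. The highest of the others gave 16 genes and their median was 3. Removal of any first-set library left 1 or 2 genes, with 2 without Ctrl replicate 2 and 1 without Ctrl replicate 1, Ctrl replicate 3 or any Chaf1a cko replicate. The count was 110 without Ctrl 3M replicate 2, 85 without Ctrl 3M replicate 3, 51 without Chaf1a cko 3M replicate 1 and 5 without Chaf1a cko 3M replicate 3.

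The 6 libraries of a set make 10 splits into 3 and 3, too few for a share under 0.05. For first-set genes the real split called 270 genes and the highest other 9, and 1 of the 10 splits reached 270. For the gene lists of the first set the real split passed 16 lists and the highest other 6, with 1 split as large. In the 3M set the real split called 2 genes and the highest other 4, and 5 of the 10 splits gave at least 2. For its gene lists the real split passed 6 and the highest other 13, and 6 splits gave at least 6.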

How the results depend on the processing

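The filter on the chemoreceptor background, the fit without Rn45s and Lars2 and the marker shares without each library were chosen after the results were seen. The 270 first-set calls became 490 with DESeq2's Wald test (246 shared) and 3 with glmTreat (Tal1, Btbd35f1 and Gm15093), which asks for more than a 1.5-fold change. Between 128 and 201 genes were called when 1 library was left out, with 132 without Ctrl replicate 2, 163 without Ctrl replicate 3, 80 higher and 57 lower without Chaf1a cko replicate 1, 128 without Chaf1a cko replicate 2 and 132 without Chaf1a cko replicate 3. The other settings gave 192 to 366 genes: 240 with library size alone (107 of them lower), 253 without a filter, 263 with DESeq2 size factors, 265 without Rn45s and Lars2, 337 above the background and 366 at 10 CPM. The 2 calls of the 3M set became 78 with DESeq2, 6 without a filter, 1 with glmTreat and 0 to 5 with 1 library left out. Lists passing in the first set fell from 16 to 8 with an estimated correlation (16 to 18 with 1 library left out). With fry 21 first-set lists passed, and the 16 were among them. In the 3M set they fell from 6 to 0 with an estimated correlation and to 0 with fry. With 1 library left out 4 to 11 passed there, with 11 without Ctrl 3M replicate 2 or Chaf1a cko 3M replicate 3. Shared calls rose from 0 to 2 with DESeq2. The 15 genes of the difference between the sets became 451 with DESeq2 and 1 to 110 with 1 library left out. Chaf1a ranged from -0.13 to 0.27 in the first set with 1 library left out (-0.02 without Ctrl replicate 1, -0.13 without Ctrl replicate 3, -0.09 without Chaf1a cko replicate 1) and from -0.16, without Ctrl 3M replicate 1, to 0.96 in the 3M set. With fewer libraries the tests have less power, and otherwise the cause was not tested. The fibroblast share differed by -0.0673 to -0.0618 percentage points in the first set and by -0.0463 to -0.000757 in the 3M set with 1 library left out.

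Of the 79 called first-set genes named, 43 stayed past the threshold in all settings but glmTreat that gave them an adjusted p, and 62 in all but glmTreat and the left-out libraries. Tal1 passed in all settings, and Btbd35f1 and Gm15093 in the 12 of 15 that gave them an adjusted p. No called gene named changed sign. Among uncalled genes, Sparc in the 3M set turned to 0.0192 without Chaf1a cko 3M replicate 2, and Rfc1 ranged from -0.0502 to 0.0399, turning to 0.0399 without Ctrl replicate 1 and 0.00179 without Chaf1a cko replicate 1. Only lists past the threshold were followed singly. The replicate numbers did not pair the samples: same-numbered libraries deviated together with r from -0.0276 to 0.0476 across genes, and not every library correlated best with its own number. With the replicate block 192 first-set genes, 0 genes of the 3M set and 0 of the difference were called, and 17 and 8 lists passed. Depth and spread limited what could be seen, as the simulated recoveries show.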

Other observations

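The values in this part were looked at after the results were seen, and no explanation is offered for them. In the first set, 2 members of an X-linked multigene family moved in opposite directions: Btbd35f1 (chromosome X, 32560055 to 32562009) was at 0.0553 CPM in Ctrl and 3.72 CPM in Chaf1a cko (log2 fold change 5.93, adjusted p 3.8e-05 in edgeR), while Btbd35f2 (chromosome X, 32278394 to 32280342) fell from 8.29 to 3.01 CPM. Gm15093, a predicted X-linked gene, fell from 3.79 to 0.141 CPM (-4.67, adjusted p 0.00015). These levels are near the background of 5.31 CPM, and reads of near-identical copies are uncertain.

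In the 3M set several genes stood far apart between the groups without passing in edgeR. Map2k4 was at 9.38, 14.8 and 11.8 CPM in Ctrl 3M and at 59.3, 49.0 and 48.3 CPM in Chaf1a cko 3M (adjusted p 0.0715). Suco was at 9.94, 6.10 and 3.60 CPM in Ctrl 3M and at 45.9, 54.5 and 54.3 CPM in Chaf1a cko 3M (adjusted p 0.0715). Myom2, which rose in the first set (0.37, adjusted p 0.000120), was at 270 against 757 CPM in the 3M set (1.49, adjusted p 0.282; called by DESeq2, adjusted p 2.6e-05). By DESeq2, Ddx3y (1.12 and -1.08) and Plin4, a lipid droplet gene (-0.58 and 1.07), were called in both sets in opposite directions.

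The ribosomal RNA precursor Rn45s took 4.56% to 7.69% of counts in the first set, highest in Chaf1a cko replicate 3, and 1.06% to 3.42% in the 3M set, highest in Ctrl 3M replicate 3. Single abundant genes of the first set stepped between levels that occurred in both groups: Igf2 was at 2153, 968 and 924 CPM in Ctrl replicates 1 to 3 and at 2137, 2163 and 907 CPM in Chaf1a cko replicates 1 to 3, relative to library totals.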
